A study of Mus musculus with 28 samples.

How the data were processed

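Bulk RNA sequencing was done on 28 samples of cells sorted from E13.5 mouse embryos of the strain Tg(Rorc-EGFP)1Ebe. Per the labels, tissue was digested with Liberase and DNase, enriched for CD45 on magnetic beads and sorted on CD45, IL7Rα, α4β7, RORγt and CD4, with F4/80, CD3e, CD19, CD8a and Ly6G used for exclusion. Polyadenylated RNA was amplified with SMART-Seq v4 and made into libraries with sample barcodes and molecular indexes. The labels give 4 populations (CLP, LTiP, LTi0, LTi4) in 2 tissues, with 4 samples per population from the embryonic periphery (EP) and 3 from the fetal liver (FL), and 2 sequencing runs of 14 samples.

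The authors aligned the reads with STAR (version not given) to GRCm38.p5 and counted them with featureCounts 1.5.2. The values are integer counts per gene, per the file headers, which name paired fragments over the exons of the Ensembl release 85 genes without a strand setting. Reads from an overlapping gene on the other strand are therefore not separated. The headers also name alignment files whose names carry the marks of duplicate removal; whether the molecular indexes were used for it is not given in the sources used here. Each of the count files held the same 48526 genes, all columns of counts were used, and 0 were left without a sample. Symbols came from GENCODE M21, which held 48058 of the gene identifiers; the other 468 kept their identifier. Coordinates are those of the GRCm38 exons in the files, from the first to the last base of each gene.

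Total counts were 3672371 to 9055071 per sample. Counts within each group varied more than counting error alone, with a chi-square per degree of freedom of at least 9.38, so tests used the spread between samples. Many counts per exonic base were high (up to 1.63 in the mean over samples; at least 0.3 in 1846 genes). Among genes between 0.3 and 1 count per base, the log2 CPM changed with the log2 depth by a median slope of -0.31. Sparser genes rose with depth instead. Their median slope was 0.379 up to 0.01 counts per base, 0.531 from 0.01 to 0.03 and 0.347 from 0.03 to 0.1.

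Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by group, which left 15961, and scaled with TMM. A negative binomial quasi-likelihood model was fitted in edgeR to all 28 samples with a mean per group and a term for the run, leaving 19 residual degrees of freedom. The comparisons were EP against FL in each population (4), each step between neighbouring populations in each tissue (6), and the difference of each step between the tissues (3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. CPM values use the TMM library sizes. For a gene without counts in a group, the fold bound sets that group at 3 counts over all its libraries, the one-sided 95% Poisson limit of a count of 0.

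Gene lists were fixed before the data were examined, and 29 were tested with camera in limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. The estimated adjusted p is given with each list. Genes called are counted both over all genes and with the p-values adjusted over the members of the list alone.

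The rule for naming genes was also fixed before the data were examined. It named the sort markers and sex-linked genes in every group. For each tissue comparison it took the 10 genes with the largest fold in each direction, with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups. For each step it took the 10 genes per direction with the largest smaller fold of both tissues, among those called the same way in both, filled up to 5 per tissue where fewer than 5 qualified. For each interaction it took the 5 genes per direction with the smallest adjusted p. It added called list members with at least 5 CPM in the higher group. Predicted genes, pseudogenes and antigen receptor segments were passed over. Alb and Afp, and the genes shared by LTi0 and LTi4, were chosen after their values were seen. Full values with coordinates are in the accompanying tables for all 159 entries.

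The workflow was tested on simulated counts with 200 changed genes per comparison and 15238 genes tested. The counts were drawn with dispersions estimated by edgeR and without a run effect. The changed genes were taken from those with a mean of at least 5 CPM, so the recovery below holds for such genes. edgeR recovered 33.7% of 2-fold and 59.4% of 4-fold changes between EP and FL CLP, 27.5% and 65.3% between FL LTi4 and LTi0, and 20.2% and 47.5% in the interaction of LTi0 and LTiP with tissue. Of its 95, 94 and 69 calls, 3, 2 and 1 were false, while DESeq2 made 64, 73 and 66 false calls of 173, 188 and 157. The 3 list tests called 20 of 20 changed and 0 of 100 unchanged simulated lists between EP and FL CLP, the comparison they were simulated for. The simulated genes were drawn independently of each other. This could therefore not test how the list tests behave with genes that vary together.

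Alternatives chosen before the data were examined were DESeq2 size factors, no filter, the DESeq2 Wald test, no run term, each run alone, a block for sets of 4 consecutive library numbers in the titles (1 library per population, not the replicate numbers used here), and leaving out each library. limma voom, leaving out the 3 FL libraries that stood apart on the second principal component, and log2 depth as a covariate were added after the data were seen. Every comparison was repeated over other splits of the same samples.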

Results

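RNA was measured in 28 libraries of sorted lymphoid cells from E13.5 mouse embryos carrying a green fluorescent reporter of RORγt. The libraries formed 8 groups, made of 4 populations, which the labels name CLP, LTiP, LTi0 and LTi4, in each of 2 tissues, the embryonic periphery (EP) and the fetal liver (FL). LTi stands for lymphoid tissue inducer, a cell type that starts the formation of lymph nodes and Peyer's patches. Each population had 4 libraries from EP and 3 from FL. Whether the replicates came from separate animals or litters is not given in the sources used here, so the p-values of genes below measure the spread between samples. The camera p-values of lists compare the list members with the other genes. With the preset correlation they do not measure how a list varies between samples. Transcripts of Xist, which marks female cells, and of the Y-linked Ddx3y were found in every library, at no less than 29.2 and 18.7 CPM (counts scaled to the library size). Between 3672371 and 9055071 counts per library were assigned to genes (median 6395071.5), and 13514 to 18833 genes had at least 1 count. After filtering, 15961 genes were tested with the edgeR quasi-likelihood F test. Genes are given with the log2 fold change, the Benjamini-Hochberg adjusted p, and the mean CPM with its standard deviation in both groups. The ± of a log2 fold change is its size divided by the square root of the F statistic. It restates the F test and is not a standard error estimated on its own. A gene is called changed below when its adjusted p was under 0.05, and fold bounds for genes without counts in a group cover counting error only.

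The first principal component held 34.4% of the variance and separated CLP and LTiP from LTi0 and LTi4 in both tissues. The second held 12.01%. On it, 3 FL libraries stood apart from the rest of their groups, LTiP replicate 3 at -79.96, LTi0 replicate 2 at -72.3 and LTi4 replicate 2 at -114. The samples came from 2 sequencing runs of 14 libraries each. EP CLP and EP LTiP were all in the first run, FL LTi0 and FL LTi4 all in the second, and the other groups were split between them. The model therefore carried a run term, for which 0 genes passed the adjusted threshold under edgeR (979 with an unadjusted p under 0.05).

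**Figure D1:**
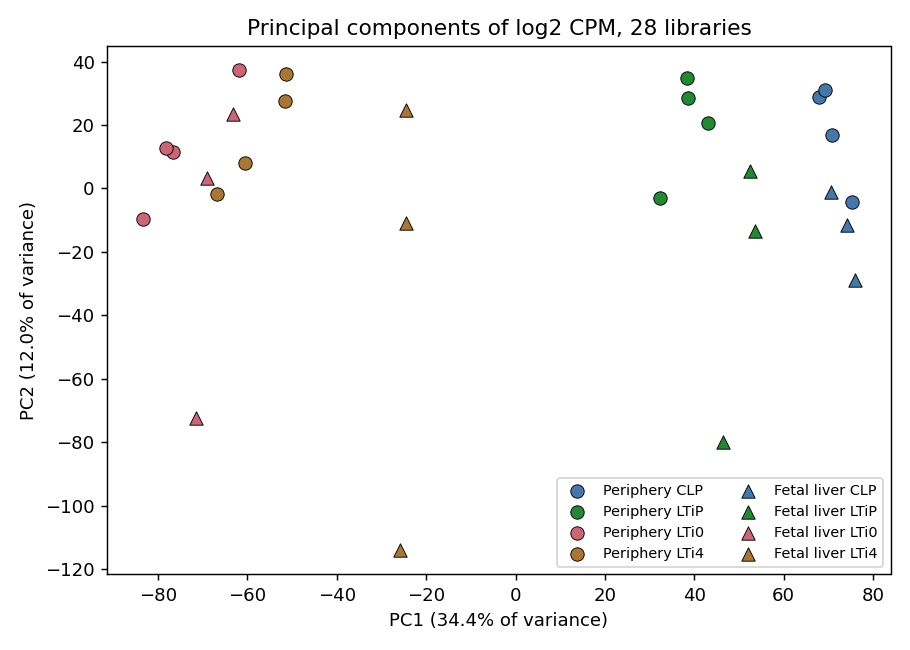
Principal components of log2 CPM over the 28 libraries. Colours mark the populations, circles EP and triangles FL.

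The cells had been sorted on CD45, IL7Rα, the integrin α4β7, RORγt and CD4, so the transcripts of these markers test the labels. Rorc, which encodes the transcription factor RORγt needed for LTi cells, rose from CLP to LTiP and from LTiP to LTi0 in both tissues. Its mean CPM was 178±30.7 in EP CLP, 398±56.0 in LTiP, 732±93.9 in LTi0 and 749±125 in LTi4, against 87.0±4.63, 371±64.9, 667±27.99 and 771±228 in FL. Cd4, which encodes the coreceptor CD4, reached 302 to 413 CPM in the 7 libraries labelled LTi0 (mean 360±37.8) and 0 to 69.5 CPM in the 7 labelled LTi4 (41.0±23.5). An exact permutation of the labels within tissues gave p 0.00143, with 2 of 1400 arrangements as extreme. The meaning of the digit in these names is not given in the sources used here, and the names LTi0 and LTi4 are used below as the labels give them. Transcripts of the lineage markers used for exclusion were low for Ly6g (at most 2.15 CPM in a library), Cd8a (at most 9.44) and Cd3e (at most 33.5). Cd19, a coreceptor of B cells, reached 141±22.5 CPM in EP CLP and 68.8±9.35 in FL CLP. Adgre1, which encodes the macrophage marker F4/80, reached 163±46.7 CPM in EP CLP.

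**Figure D2:**
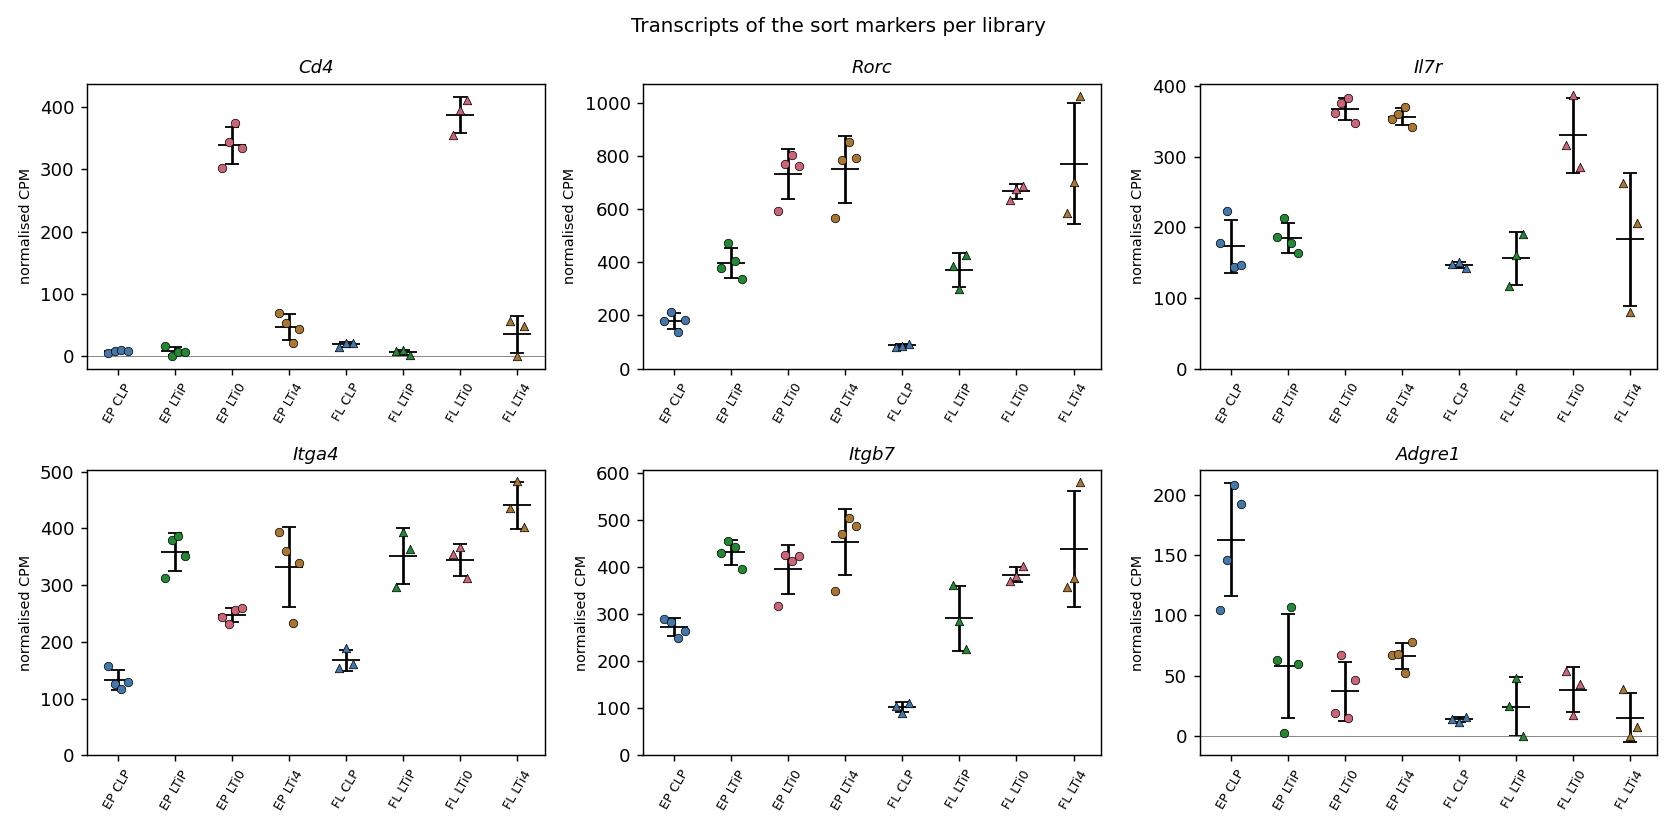
Transcripts of the sort markers per library, in normalised CPM. Horizontal lines are group means and bars standard deviations.

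**Figure D3:**
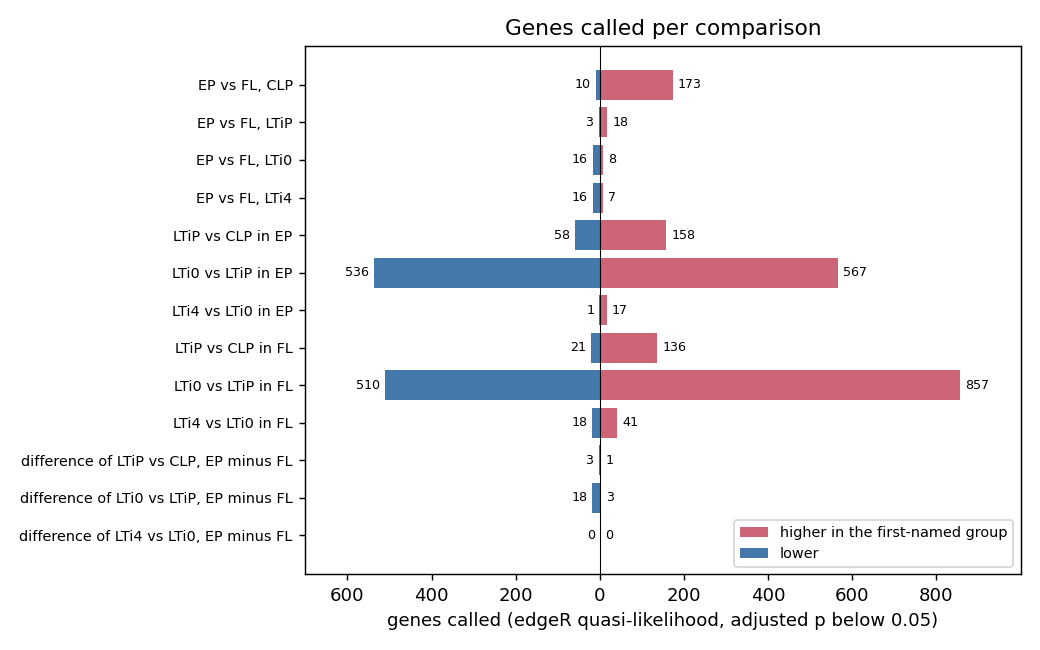
Genes called higher or lower in each comparison by edgeR.

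Between EP and FL CLP, 183 genes were called, 173 higher in EP and 10 lower (1432 with an unadjusted p under 0.05). The genes with the largest changes included several of tissue macrophages. Mrc1 encodes the mannose receptor, Stab1 a scavenger receptor, Fcrls an Fc receptor-like protein of microglia, and C1qa a chain of the complement component C1q. Slco2b1 encodes an organic anion transporter, Gas6 a ligand of TAM receptors in the clearance of dead cells, and Ccl12 a chemokine that attracts monocytes. Hba-x and Hbb-y encode the embryonic globin chains of primitive red cells.

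Mrc1 (chromosome 2, 14229392 to 14332057, plus strand, GRCm38) was higher in EP CLP by log2 7.85±1.80 (adjusted p 0.0373), at 126±58.3 against 0.577±0.531 CPM. C1qa (chromosome 4, 136895917 to 136898803, minus strand) was higher by 7.03±1.56 (0.0217; 79.0±29.1 against 1.02±1.21 CPM). Stab1 reached 267±162 against 3.27±2.77 CPM (6.18±1.47, adjusted p 0.0373) and Fcrls 138±42.7 against 1.90±2.35 (6.14±1.498, 0.0432). Slco2b1 (5.65±1.23, 0.0184), Gas6 (6.36±1.47, 0.0289) and Ccl12 (6.60±1.39, 0.0206) were also higher. Myh13, a myosin heavy chain of skeletal muscle, had no count in FL CLP and 27.5±14.1 CPM in EP CLP, at least 182-fold more (adjusted p 0.0289). Hba-x (6.12±1.04, 0.00271; 30.4±17.3 against 0.490±0.849 CPM) and Hbb-y (5.79±1.25, 0.0176; 60.2±32.0 against 1.34±1.90) were higher in EP. Reads of these globins, and of the 3 chains of C1q, can be shared with related genes, so the assignment to a single gene is uncertain. Of the genes lower in EP CLP, Dlk1 (chromosome 12, 109452823 to 109463336, plus strand), which encodes a Notch ligand-like protein of fetal tissues, changed by -1.35±0.21 (adjusted p 0.000848; 43.0±8.60 against 105±19.7 CPM). Gcsam (-2.60±0.54, 0.0137), which encodes a signalling adaptor of germinal centre B cells, and the tetraspanin gene Tspan6 (-1.65±0.37, 0.0244) were lower too. So were Spns2 (-1.48±0.29, 0.00880), an exporter of sphingosine 1-phosphate, and Cd27 (-0.94±0.20, 0.0173), a receptor of lymphoid progenitors. Dnmt3b (-0.76±0.14, 0.00549), a de novo DNA methyltransferase, and Cnn3 (-0.61±0.15, 0.0468), an actin-binding calponin, followed, as did Klhdc2 (-0.65±0.14, 0.0192), part of a ubiquitin ligase, and the phosphatase gene Ptpn7 (-0.41±0.10, 0.0433).

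Of the preset macrophage list, 9 of 19 measured genes were higher in EP CLP and 0 lower (11 higher when adjusted over the list alone). The list's adjusted p was 6.90e-21 by camera with a preset correlation and 0.000237 with an estimated one. Beside C1qa and Mrc1, C1qc and C1qb, Aif1 (53.9 against 6.01 CPM), Cd68, Apoe, Lgmn and Ctsb were called. The list of transcription factors and receptors of innate lymphoid precursors had 5 of 17 genes higher (8 over the list alone; adjusted p 3.97e-12, estimated 6.85e-06). These were Maf (3.09, 64.8 against 9.70 CPM), Tox2 (3.59), Cxcr6 (3.91), Tcf7 (1.94, 37.4 against 9.67 CPM) and Gata3 (1.64). The LTi effector list had 5 of 24 higher (9; 3.98e-09, estimated 0.00115), among them Cd83, Ccr6, Nrp1 and Rorc (0.88, adjusted p 0.0160). Of the chemotaxis and adhesion list 7 of 25 were higher (10; 3.14e-09, estimated 0.000509), including Itgb7 (1.36, adjusted p 0.000241; 272 against 102 CPM), which encodes the β7 chain of the sorted integrin. Of the class II antigen presentation list 3 of 9 were higher (4; 6.87e-07, estimated 0.0118), H2-Aa, H2-Eb1 and Cd74. The TNF and NF-κB list had 2 of 21 higher (6; 1.14e-10, estimated 0.0225) and the T lineage list 1 of 19 (3; 0.00317, estimated 0.0225). The erythroid list, with 2 of 18 higher, lost its call with an estimated correlation (adjusted p 0.202), as did the mesenchyme list, with 1 of 12 (0.165). Within the first run alone, with 4 EP libraries and 1 FL library assumed to vary as the other groups do, 135 genes were called. Leaving out FL CLP replicate 3 left 95 genes and leaving out FL CLP replicate 1 left 119.

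**Figure D4:**
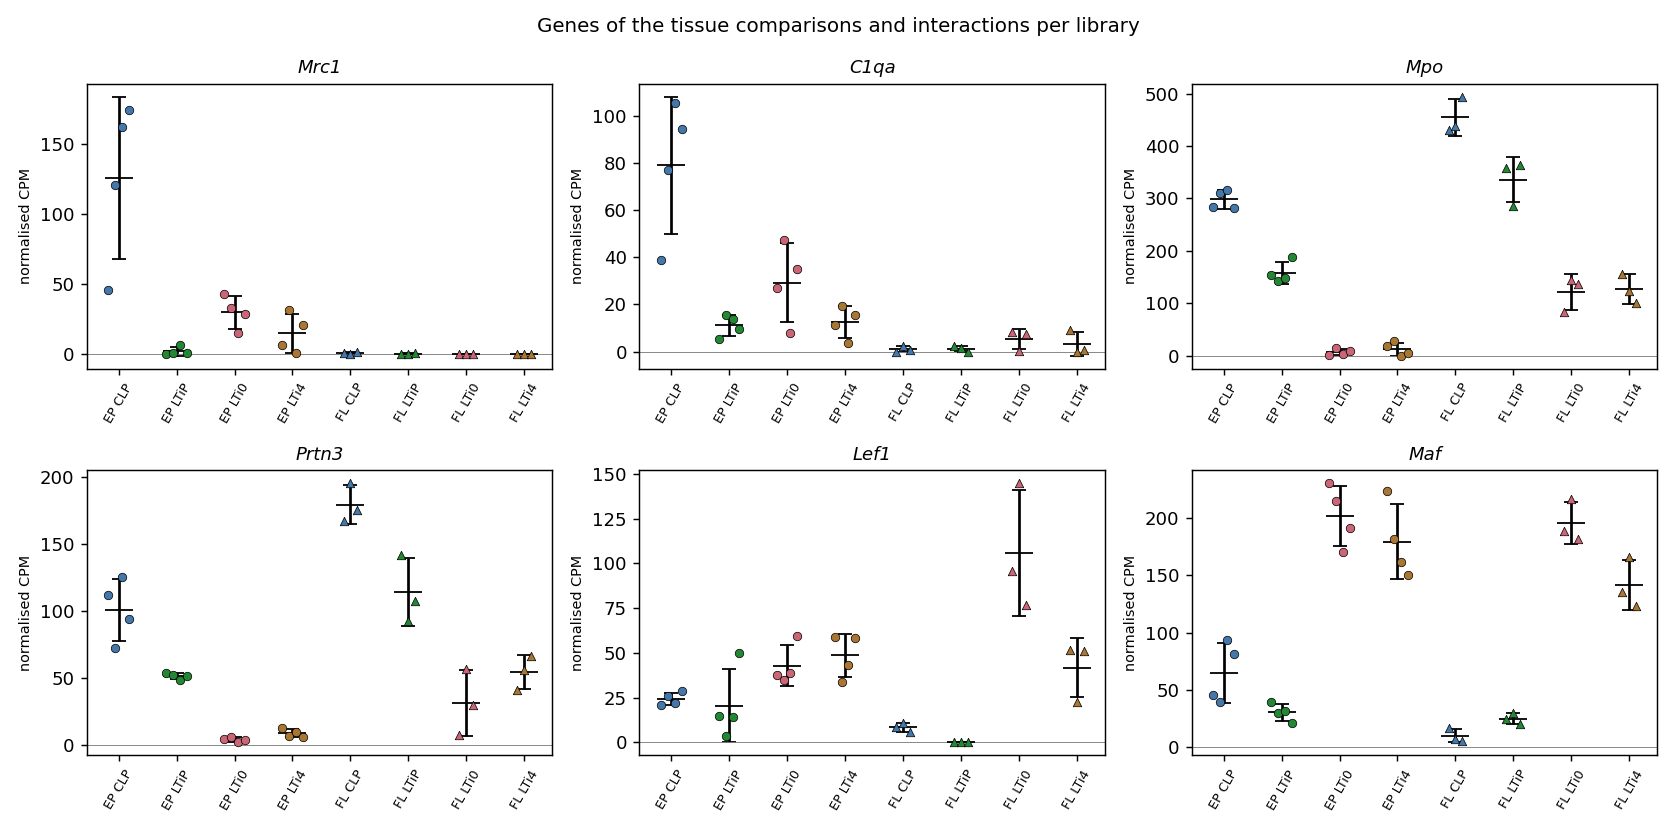
Genes of the tissue comparisons and of the interactions per library, in normalised CPM, with group means and standard deviations.

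Between EP and FL LTiP, 21 genes were called, 18 higher in EP and 3 lower (1401 unadjusted). Lef1 encodes a transcription factor of the Wnt pathway in lymphoid progenitors, and Dll1 a ligand of Notch receptors. Lta encodes lymphotoxin α, a cytokine that lymph node formation needs. Id3, an inhibitor of E proteins, and Rasd1, a small GTPase, led the genes lower in EP.

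Lef1 (chromosome 3, 131110471 to 131224356, plus strand) had no count in the 3 FL LTiP libraries and 20.5±20.2 CPM in EP LTiP, at least 137-fold more (adjusted p 0.000409; 71.9-fold without EP LTiP replicate 4). Dll1 was higher by log2 2.76±0.51 (0.0180; 63.2±15.3 against 8.24±4.47 CPM) and Lta by 1.53±0.26 (0.00995; 36.9±8.89 against 11.5±6.64). Gpr18, a receptor of lymphocytes (2.71±0.42, 0.00457), and H2-Eb1, a class II chain (2.41±0.42, 0.0105; 106±20.8 against 22.5±7.90 CPM), were higher. So were Bhlhe40, a transcription factor of activated lymphocytes (1.96±0.29, 0.00430; 142±28.1 against 38.7±7.48 CPM), and Mdk, the growth factor midkine (1.67±0.29, 0.0104). Zcchc18 (2.77±0.54, 0.0293), a zinc finger gene, Agpat3 (2.09±0.29, 0.00141), an acyltransferase of phospholipid synthesis, and Arsb (1.496±0.29, 0.0256), a lysosomal sulfatase, were also called. Id3 (chromosome 4, 136143497 to 136145755, plus strand) changed by -2.91±0.38 (adjusted p 0.000992), from 124±17.3 CPM in FL to 15.8±9.99 in EP. Rasd1 changed by -2.32±0.37 (0.00543) and Cnn3 by -0.73±0.15 (0.0383). Of the precursor list 1 of 17 was higher (6 over the list alone; adjusted p 4.76e-05, estimated 0.00319) and of the class II list 1 of 9 (5; 7.51e-07, estimated 0.0141). The T lineage list rose with no single gene called (1 over the list alone; 0.000458, estimated 0.0141). The LTi effector list, with 1 of 24 higher (6 over the list alone), lost its call with an estimated correlation (adjusted p 0.0764), and so did the TNF and NF-κB list, with 1 of 21 higher (0.112), and the macrophage list, with 0 of 19 called and 17 with a positive log2 fold change (adjusted p 0.0034, estimated 0.189). Within the first run 2361 genes were called, a comparison that rests on 1 FL library assumed to vary as the other groups do. The FL library of the first run was replicate 3, which stood apart on the second principal component. Leaving out single FL LTiP libraries gave 53 genes (replicate 1), 67 (replicate 2) and 6 (replicate 3). Leaving out FL LTi4 replicate 2, FL CLP replicate 1 or FL CLP replicate 3 gave 35, 33 and 32.

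Between EP and FL LTi0, 24 genes were called, 8 higher in EP and 16 lower (1372 unadjusted). Genes of neutrophil granules led those lower in EP. Mpo encodes myeloperoxidase, Prtn3 proteinase 3 and Elane neutrophil elastase, 3 proteins stored in the granules of neutrophil precursors. Itgam encodes the integrin chain CD11b, Ncf1 a subunit of the phagocyte NADPH oxidase, and Btk a kinase of B cell and myeloid signalling. Cpa3, a carboxypeptidase of mast cells, and the embryonic globin gene Hbb-y were higher in EP.

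Mpo (chromosome 11, 87793581 to 87804413, plus strand) changed by log2 -3.88±0.64 (adjusted p 0.00781), with 7.11±6.01 CPM in EP against 122±33.9 in FL. Prtn3 (chromosome 10, 79874476 to 79883174, plus strand) changed by -2.81±0.44 (0.00590; 4.02±1.76 against 31.5±24.6 CPM). Elane had no count in EP and 15.7 CPM in FL, at least 141-fold more in FL (adjusted p 0.0392; 59-fold without FL LTi0 replicate 2). Itgam (-1.98±0.31, 0.00520; 16.03±7.37 against 69.6±6.11 CPM), Ncf1 (-0.81±0.13, 0.00648) and Btk (-1.06±0.21, 0.0254) were lower in EP. Tbc1d2, which acts on Rab GTPases (-2.58±0.37, 0.00194; 23.0±6.99 against 151±37.6 CPM), and the galectin-like Grifin (-2.56±0.37, 0.00194) were lower as well. Further genes lower in EP were Adgrg1 (-2.13±0.39, 0.0162), an adhesion receptor, and Plppr3 (-1.87±0.36, 0.0233), a phospholipid phosphatase-related gene. Pygm (-1.58±0.26, 0.00718), the muscle form of glycogen phosphorylase, was lower too. Hbb-y (chromosome 7, 103851749 to 103853216, minus strand) was higher by 7.67±1.39 (adjusted p 0.0141; 44.9±17.8 against 0.241±0.418 CPM). Hba-x had no count in FL and 17.3 CPM in EP, at least 130-fold more (0.00194). Cpa3 was higher by 2.77±0.49 (0.0125; 59.3±10.4 against 10.4±7.16 CPM). No list kept its call with an estimated correlation. The granulocyte and monocyte list, with 3 of 19 lower in EP (6 over the list alone; adjusted p 0.000202 with the preset correlation), had an estimated adjusted p of 0.189. The erythroid list, with 2 of 18 higher (0.000534), also had an estimated adjusted p of 0.189. Alb, a transcript of hepatocytes, had no count in the EP libraries and reached 114 CPM in 1 FL LTi0 library, replicate 1. Within the second run, 1 gene was called from 2 EP and 3 FL libraries, and leaving out FL LTi0 replicate 2 or replicate 1 gave 14 and 48 genes.

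Between EP and FL LTi4, 23 genes were called, 7 higher in EP and 16 lower (1774 unadjusted). Mpo, Prtn3, Adgrg1, Ncf1 and Cox6a2 were lower in EP in both LTi0 and LTi4, where independent draws would give 0.0160 shared genes. These comparisons may not be independent, since their libraries share sets of consecutive library numbers. With the group means removed, 21 of all 28 libraries correlated best with a library of their own set, among the other populations of their tissue. S100a8 encodes a calcium-binding protein of neutrophils, and Cox6a2 a subunit of cytochrome c oxidase in muscle. Dab2 encodes an endocytic adaptor, Ski a repressor of TGF-β signalling, and Nfatc1 a transcription factor of calcium signalling in lymphocytes.

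Mpo changed by log2 -3.17±0.58 (adjusted p 0.0216; 12.7±12.4 CPM in EP against 127±27.8 in FL) and Prtn3 by -2.43±0.44 (0.0216; 8.88±3.10 against 54.6±12.8). S100a8 (chromosome 3, 90668978 to 90670035, plus strand) changed by -5.57±1.11 (0.0413; 0.516±1.03 against 25.03±5.98 CPM). Id3 changed by -2.14±0.38 (0.0216; 14.7±2.55 against 67.0±10.2 CPM), Cox6a2 by -2.20±0.44 (0.0413) and Adgrg1 by -2.06±0.38 (0.0216). Fbn2, a fibrillin of elastic fibres, had no count in EP and 5.26, 83.5 and 14.1 CPM in the FL libraries, at least 293-fold more in FL (adjusted p 0.0431). This call ended on leaving out any of 20 single libraries, with an adjusted p up to 0.138 and a bound of 82.9-fold without FL LTi4 replicate 2. It also ended without the 3 FL libraries that stood apart (0.0506), with log2 depth as a covariate (0.0585) and within the second run (0.96). Tnni2 (-1.40±0.27, 0.0319), a troponin of fast muscle, and Gcat (-1.07±0.19, 0.0216), an enzyme of threonine breakdown, were lower in EP. Themis2 (-1.02±0.19, 0.0216), an adaptor of B cell signalling, was lower too. Dab2 (chromosome 15, 6299788 to 6440712, plus strand) was higher by 4.20±0.79 (adjusted p 0.0310; 123±36.2 against 6.18±9.78 CPM). Ski (3.71±0.76, 0.0477; 158±41.0 against 13.2±4.56 CPM) and Nfatc1 (0.72±0.10, 0.00738; 598±62.7 against 365±30.2 CPM) were higher, as was Smap2, a GTPase-activating protein of Arf (0.74±0.13, 0.0216). Of the granulocyte and monocyte list 3 of 19 were lower in EP (12 over the list alone; adjusted p 3.68e-10, estimated 0.0189). Of the G2/M list 1 of 25 was lower, Aurka, a mitotic kinase (-0.61, adjusted p 0.0216), and 11 over the list alone (1.07e-10, estimated 0.0208). Lower values of the ribosomal protein list, with 0 of 79 genes called, were lost with an estimated correlation (adjusted p 0.503). Within the second run edgeR called 0 genes from 2 EP and 3 FL libraries (717 unadjusted), and over all libraries limma voom called 52 higher and 29 lower, which turned the balance. Leaving out FL LTi4 replicates 1, 2 and 3 gave 247, 9 and 0 genes (1575 unadjusted in the last), EP LTi4 replicates 1, 2 and 4 gave 2, 11 and 3, and FL LTi0 replicate 2, EP CLP replicate 1, EP LTiP replicate 4 and FL LTiP replicate 3 gave 41, 14, 15 and 36.

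From CLP to LTiP, 216 genes changed in EP (158 higher and 58 lower; 1333 unadjusted) and 157 in FL (136 and 21; 1224 unadjusted). In both tissues 69 genes rose and 5 fell, where independent draws would give 1.35 and 0.0763. Zbtb16 encodes PLZF, a transcription factor of innate lymphoid precursors. Tcf7 encodes TCF1, and Rora and Gata3 further factors that these precursors use. Ccl5 and Ccr8 encode a chemokine and a chemokine receptor of lymphocytes, and Il17rb a receptor for interleukin 25. Igll1, a chain of the surrogate light chain of B cell precursors, fell.

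Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) rose by log2 3.28±0.21 in EP (adjusted p 1.83e-09; 365±36.2 against 37.4±3.52 CPM) and 4.51±0.26 in FL (3.39e-10; 224±16.3 against 9.67±5.58). Zbtb16 (chromosome 9, 48654311 to 48835945, minus strand) rose by 5.35±0.72 in EP (7.80e-05; 61.3±8.57 against 1.41±1.72 CPM) and 4.14±0.77 in FL (0.00476; 41.3±9.97 against 2.36±3.31). Rora rose by 4.34±0.56 and 3.72±0.66 (4.61e-05 and 0.00284). Arg1, which encodes arginase 1, rose by 3.21±0.36 and 3.65±0.44 (9.17e-06 and 2.88e-05). Ccl5 rose by 7.03±0.56 in EP (7.09e-08; 60.7±8.44 against 0.427±0.317 CPM) and 6.88±0.68 in FL (1.68e-06; 26.4±7.57 against 0.232±0.402). Ccr8 (4.96±0.87 and 4.80±1.07), Il17rb (4.49±1.03 and 5.74±1.32) and Tnfrsf9, a costimulatory receptor (4.03±0.40 and 5.19±0.54), rose in both. Cd3g, a chain of the T cell receptor complex, rose by 3.47±0.31 (3.08e-07) and 5.03±0.41 (1.19e-07). Rxrg, a retinoid X receptor, rose by 5.63±1.17 in EP (0.0102), and in FL had 24.5±5.86 CPM in LTiP against 0.0915±0.159 in CLP. Igll1 fell, by log2 -4.34±0.69 in EP (0.00211; 6.85±5.16 against 139±19.5 CPM) and -3.44±0.77 in FL (0.0428). Rab3il1, an exchange factor of Rab3, changed by -1.71±0.21 (3.02e-05) and -1.10±0.24 (0.0235). St3gal6, a sialyltransferase (-1.31±0.26 and -1.35±0.30), Egfl7, a secreted protein of endothelium and progenitors (-0.97±0.19 and -0.98±0.22), and Klf3, a repressor (-0.69±0.14 and -0.95±0.16), also fell in both.

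The list of innate lymphoid precursor genes had 11 of 17 higher in EP and 13 in FL (13 and 13 over the list alone; estimated adjusted p 3.64e-08 and 3.93e-09), with 1 lower in each, Maf in EP and Lef1 in FL. The T lineage list had 7 and 3 of 19 higher (13 and 12; estimated 8.47e-08 and 3.90e-07) and the NK and ILC1 list 8 and 3 of 15 (9 and 8; 2.29e-05 and 0.000217). The ILC2 list had 4 and 4 of 10 higher (6 and 5; estimated 0.000424 and 0.000385), and the class II list 3 and 3 of 9 (6 and 4; 0.000469 and 0.00152). The chemotaxis and adhesion list had 4 and 7 of 25 higher (4 and 10; estimated 0.0181 and 0.000175). B lineage genes fell, 2 and 3 of 17 (5 and 3 over the list alone; estimated 9.42e-05 and 0.000598). In EP the granulocyte and monocyte list had 3 of 19 lower (9 over the list alone, estimated 0.000220) and the macrophage list 5 of 19 lower (11, estimated 0.00104). Adgre1, at 58.3±42.8 CPM in EP LTiP against 163±46.7 in CLP, was not called by edgeR (adjusted p 0.856). In FL the granulocyte and monocyte list had 0 lower and lost its call with an estimated correlation (adjusted p 0.0594). In EP the mast cell and basophil list rose with 1 of 11 higher (2; estimated 0.00699) and the Notch target list with 2 of 13 (3; estimated 0.0331). In FL the LTi effector list rose with 2 of 24 higher (7; estimated 0.0125). Within the first run 480 genes were called in EP and 1102 in FL (187 higher and 915 lower, against 136 and 21 over all libraries), the latter from 1 library per group, and within the second run 70 in FL. The FL LTiP library of the first run was replicate 3, which stood apart on the second principal component. Leaving out FL CLP replicate 1 left 104 genes in FL.

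From LTiP to LTi0, 1103 genes changed in EP (567 higher and 536 lower; 2911 unadjusted) and 1367 in FL (857 and 510; 3614 unadjusted). In both tissues 424 genes rose and 214 fell, where independent draws would give 30.4 and 17.1. Il23r encodes the receptor of interleukin 23, and Il22 and Il17a encode cytokines that RORγt-dependent lymphoid cells release. Cxcr5 and Ccr6 encode chemokine receptors of LTi cells, and Lta and Ltb the lymphotoxin chains. Genes of progenitors, such as Flt3, Mef2c and Bcl11a, and of basophils, such as the protease gene Mcpt8, fell.

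Il23r (chromosome 6, 67422932 to 67491855, minus strand) had no count in LTiP of either tissue and 108±16.6 CPM in EP LTi0 and 112±19.7 in FL LTi0, at least 789-fold and 749-fold more (adjusted p 0.000440 and 0.00119). Il22 (chromosome 10, 118204942 to 118210047, plus strand), whose reads can be shared with the near copy Iltifb, rose by log2 9.20±0.74 in EP (7.35e-08; 138±16.3 against 0.189±0.377 CPM). In FL it had no count in LTiP and 99.6±13.98 CPM in LTi0, at least 665-fold more (3.61e-07). Serinc2, which encodes a membrane protein, had no count in EP LTiP and 302±45.2 CPM in LTi0, at least 2220-fold more (5.65e-10), and rose by 9.98±0.62 in FL (7.86e-09). Il17a had no count in EP LTiP and 44.5±9.64 CPM in LTi0, at least 327-fold more (0.00118), and 44.8±13.2 against 0.0498±0.0863 CPM in FL. Foxs1, a forkhead factor, rose from no count to 65.4±15.6 CPM in EP and 25.8±22.8 in FL, at least 480-fold and 173-fold (115-fold without FL LTi0 replicate 3). Ip6k3, an inositol phosphate kinase, rose from no count at least 302-fold and 215-fold, Gnb3, a G protein subunit, at least 187-fold and 245-fold (161-fold without FL LTi0 replicate 3), and Gtsf2, a zinc finger gene, at least 218-fold and 241-fold. FL LTi0 replicate 2 had no count of Foxs1 or of Gnb3. Plekhs1, a pleckstrin homology gene, had no count in EP LTiP (at least 429-fold more in LTi0) and 51.8±9.43 against 0.0498±0.0863 CPM in FL. Cacna1g, a calcium channel, had 92.0±16.3 against 0.0377±0.0755 CPM in EP and 68.1±17.4 against 0.114±0.115 in FL.

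Mcpt8 (chromosome 14, 56082166 to 56085216, minus strand) had no count in LTi0 of either tissue and 47.2±10.02 CPM in EP LTiP and 75.7±34.0 in FL LTiP, at least 424-fold and 571-fold more in LTiP. Il6, the cytokine interleukin 6, was at least 271-fold and 617-fold (342-fold without FL LTiP replicate 2) higher in LTiP, again with no count in LTi0. Jchain, the joining chain of antibodies that lymphoid progenitors also transcribe, changed by -6.31±1.10 in EP (adjusted p 0.000632) and -5.58±1.21 in FL (0.00448). Il12a, a chain of interleukins 12 and 35, changed by -7.01±1.05 in EP (0.000111) and -5.50±1.01 in FL (0.00103). Ly6d, a surface marker of B-biased progenitors, changed by -5.85±1.35 in EP (0.00785) and -7.44±1.49 in FL (0.00231), and Kcng1, a potassium channel subunit, by -7.04±1.20 and -6.86±1.31. Ddit4l, a regulator of mTOR, fell by 7.30±1.28 in EP (0.000774) and had no count in FL LTi0 (at least 199-fold more in LTiP, 101-fold without FL LTiP replicate 3). Nuak2, a stress-activated kinase, fell by 5.47±1.56 in EP (0.0376) and had no count in FL LTi0 (at least 176-fold, 64.5-fold without FL LTiP replicate 1). Stc1, the hormone stanniocalcin 1, had 20.6±12.7 CPM in EP LTiP against 0.0838±0.168 in LTi0, and no count in FL LTi0 (at least 264-fold, 100-fold without FL LTiP replicate 3). Drc7, a gene of the ciliary axoneme, had 25.1±10.8 against 0.0548±0.110 CPM in EP and fell by 5.70±1.45 in FL (0.0170).

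The LTi effector list had 20 of 24 genes higher in EP and 19 in FL (20 and 19 over the list alone; estimated adjusted p 1.55e-05 and 5.73e-06). Beside the genes above, Cxcr5 rose to 352 and 350 CPM, Il1r1, a receptor of interleukin 1, to 390 and 351, Lta to 207 and 215, and Tnfsf11, the cytokine RANKL, to 186 and 173. The innate lymphoid precursor list had 6 and 13 of 17 higher (10 and 14; estimated 4.67e-05 and 2.94e-06). In FL the TNF and NF-κB list had 12 of 21 higher (17; estimated 0.0218), among them Relb and Nfkb2 of the noncanonical pathway. In EP it had 8 higher and lost its call with an estimated correlation (adjusted p 0.115). The chemotaxis and adhesion list had 9 of 25 higher and 2 lower in FL (estimated 0.0218), with Ccr9 and Sell among the lower genes. In EP it had 7 higher and 3 lower, without a call at an estimated correlation (adjusted p 0.115). The stem and progenitor list had 10 of 23 genes lower in EP (14 over the list alone; estimated 0.000223) and 10 lower with 1 higher, Kit, in FL (12; estimated 0.00283). Flt3 changed by -1.91 in EP and -1.27 in FL, Bcl11a by -2.83 and -2.06, and Mef2c by -2.07 and -1.79. The B lineage list had 10 of 17 lower in EP (13; estimated 0.00153) and 5 in FL (8; estimated 0.0497), while Blk, a kinase of B cells, rose by 3.14 and 2.90. The mast cell and basophil list had 3 of 11 lower in EP (estimated 0.0355), and its 3 lower genes in FL lost the list call (estimated adjusted p 0.0641). Within the first run 1515 genes were called in EP and within the second run 351 in FL. Leaving out EP LTi0 replicate 3 left 663 genes in EP.

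From LTi0 to LTi4, 18 genes changed in EP (17 higher and 1 lower; 897 unadjusted) and 59 in FL (41 and 18; 1966 unadjusted). In both tissues 7 genes rose, where independent draws would give 0.0437, and 0 fell in both. Flt3 encodes a cytokine receptor of lymphoid progenitors and Flt1 a receptor of vascular endothelial growth factor. Cavin2 encodes a coat protein of caveolae, Fgd2 an exchange factor of Cdc42 in antigen-presenting cells, and Sp100 a nuclear body protein. Tsc22d1 encodes a leucine zipper regulator of transcription.

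Flt3 (chromosome 5, 147330741 to 147400489, minus strand) rose by log2 1.28±0.12 in EP (adjusted p 5.98e-06; 247±27.2 against 102±10.7 CPM) and 0.97±0.14 in FL (0.00142; 299.5±28.6 against 153±16.4). Cavin2 (chromosome 1, 51289126 to 51302960, plus strand) rose by 5.43±0.95 in EP (0.0137; 66.7±26 against 1.82±2.90 CPM) and 4.88±1.00 in FL (0.0308; 95.7±34.2 against 3.23±5.59). Flt1 rose by 2.06±0.37 (0.0168) and 2.14±0.42 (0.0220), and Ncf1 by 1.09±0.11 (1.37e-05) and 0.92±0.13 (0.00142). Fgd2 rose by 1.31±0.19 (0.00140) and 1.54±0.21 (0.00142), Sp100 by 1.26±0.17 (0.000779) and 1.18±0.19 (0.00508), and Tsc22d1 by 0.81±0.15 (0.0275) and 1.07±0.18 (0.00508). In FL, Gas7, a cytoskeletal regulator, fell by 2.86±0.42 (0.00183; 4.56±2.90 against 33.7±6.94 CPM), and Fam210b, a mitochondrial protein, fell by 2.16±0.43 (0.0246). Rasd1 fell by 2.10±0.38 (0.0123), Prdm11, a transcriptional repressor, fell by 1.54±0.30 (0.0190), and Mrs2, a mitochondrial magnesium channel, fell by 1.37±0.24 (0.0107). Cd4 itself, 339±29.8 against 46.2±20.7 CPM in EP and 388±29.4 against 34.2±29.9 in FL, was not called by edgeR (adjusted p 0.213 and 0.0969). In EP the stem and progenitor list had 2 of 23 higher, Flt3 and Bcl11a (8 over the list alone; adjusted p 3.60e-09, estimated 0.00252). In FL it had 2 higher and 1 lower, and the call was lost with an estimated correlation (adjusted p 0.116). Within the first and second run 38 and 6 genes were called in EP, and within the second run 1 in FL, while limma voom called 91 higher and 191 lower in FL over all libraries. Leaving out FL LTi0 replicate 2, EP LTi0 replicate 4 or EP LTi4 replicate 4 gave 40, 35 and 11 genes in EP, and leaving out FL LTi0 replicates 1 and 2 or FL LTi4 replicates 1 and 2 gave 112, 21, 272 and 30 in FL.

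The interaction tests asked which steps differed between the tissues. For CLP to LTiP 4 genes were called, 1 with a more positive change in EP and 3 with a more negative one (761 unadjusted). Lef1 differed (adjusted p 0.0128; FL LTiP had no count, so no fold is given), with means of 24.4 and 20.5 CPM in CLP and LTiP of EP and 8.43 and 0 in FL. Maf, a factor of lymphoid cytokine production, differed by -2.47±0.40 (0.0147; 64.8 and 30.3 CPM in EP, 9.70 and 24.7 in FL). Hmgn3, a nucleosome-binding protein (-1.85±0.25, 0.00298), and Jaml, an adhesion molecule of lymphocytes (-1.77±0.29, 0.0175), also differed. The macrophage list changed more negatively in EP, with 0 of 19 genes called (6 over the list alone; adjusted p 1.36e-11, estimated 0.0125). Within the first run 777 genes were called (719 more positive in EP and 58 more negative), with 1 FL library per group, and with a replicate block Lef1 was not called (adjusted p 0.0603). The FL LTiP library of the first run was replicate 3, which stood apart on the second principal component. Leaving out FL CLP replicate 1 or FL LTiP replicate 3 gave 9 genes each, and FL LTiP replicate 1 or FL CLP replicate 3 gave 2 each. Without FL LTiP replicate 1 or 2 Lef1 was not called by edgeR (adjusted p 0.0612 and 0.0517).

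For LTiP to LTi0 21 genes were called, 3 with a more positive change in EP and 18 with a more negative one (1431 unadjusted). Lef1 differed as well (adjusted p 0.000184), as it rose from no count to 106±35.1 CPM in FL and went from 20.5±20.2 to 42.9±11.3 in EP. Itgam differed by -3.06±0.42 (0.00116; 77.5 to 16.03 CPM in EP, 42.8 to 69.6 in FL) and Ncf1 by -1.02±0.17 (0.0170). Tbc1d2 (-2.85±0.48, 0.0170) and Grifin (-2.84±0.48, 0.0170) differed in the same direction. Lta rose more in FL (-1.76, 0.0235), and so did Cxcr3, a chemokine receptor (-2.03, 0.0213). Ms4a6c, a gene of myeloid cells (6.45±1.12, 0.0200), and Cmah, an enzyme of sialic acid (6.38±1.24, 0.0309), had the opposite sign, with 4 and 5 counts in all of FL LTi0. So had Hba-x, with no count in FL LTi0 (adjusted p 0.0235; 87.9 to 17.3 CPM in EP, 31.4 to 0 in FL). The innate lymphoid precursor list rose less in EP, with 1 of 17 genes called (1 over the list alone; adjusted p 0.000177, estimated 0.00803). The T lineage, interferon response and class II lists also changed more negatively in EP, with 0 genes called in each (1, 2 and 4 over the list alone) and an estimated adjusted p of 0.0349 for each. Neither run held all 4 groups compared here. Leaving out EP LTi0 replicates 1 and 3, EP LTiP replicate 2, FL LTi0 replicates 1 and 2 and FL LTiP replicates 2 and 3 gave 8, 13, 9, 32, 13, 45 and 11 genes.

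For LTi0 to LTi4 edgeR called 0 genes as different between the tissues (1131 unadjusted), while DESeq2 called 121 and limma voom 2. No list kept its call with an estimated correlation, the G2/M list ending at an adjusted p of 0.451. Within the second run 0 genes were called by edgeR (691 unadjusted). Leaving out FL LTi0 replicate 1, FL LTi4 replicate 1, EP LTi0 replicate 2 and EP LTi4 replicate 4 gave 9, 5, 3 and 2 genes, and EP LTi4 replicate 1, EP LTi0 replicate 4, EP CLP replicate 4, FL LTiP replicate 1 and FL LTi0 replicate 3 gave 1 each.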

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

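The tests of exchanged names, saturation, macrophage RNA, the run difference of the macrophage genes, whole-liver RNA and granulocyte precursors below were chosen only after the results they concern were seen.

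Cd4 transcripts were high in the libraries labelled LTi0 and low in those labelled LTi4, and 0 of the 7 libraries labelled LTi4 reached the lowest library labelled LTi0. Saturation of counts by duplicate removal lowers the counts of dense genes, so it would shrink an excess of Cd4 in LTi0 rather than make it. Its test therefore could not decide. Of 2143 other genes with 0.3 to 1 counts per exonic base in LTi0, 95% had a log2 ratio of LTi4 to LTi0 above -0.322 (median 0.011). That of Cd4 was -3.133. A difference between sequencing runs was argued against, since the ratio of the groups in EP was 11.3 in the first run and 5.3 in the second. Whether the names of the LTi0 and LTi4 groups were exchanged cannot be told apart from names that follow something other than the CD4 level, because the names cover whole groups and no single library stood out of place. A difference between transcript and surface protein remains open and was not tested.

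Macrophage genes were higher in the CLP libraries of EP. As a test of LTi-lineage cells as their source, 9 of 9 called ones had a higher mean in EP CLP than in each other EP group. These 9 were chosen as high in the same EP CLP libraries, which favours this result, so the count does not decide. The whole preset list, whose members were fixed beforehand, was lower in EP LTiP than in EP CLP, which goes against LTiP cells as the source. This comparison is not independent either, since the list was taken up because it was high in these EP CLP libraries. LTi-lineage cells are not excluded from the libraries, where the innate lymphoid precursor and LTi effector lists (estimated adjusted p 6.85e-06 and 0.00115), Itgb7, Rorc and Tcf7 were higher too. A difference between sequencing runs was argued against, since in EP LTi0 and LTi4, which were split between the runs, the log2 ratio of the runs was at most 0.249 of a gene's log2 fold change in CLP. Macrophages or their RNA cannot be told apart from an untested CLP state in EP that transcribes these genes. Some of the genes were not particular to EP CLP. Mrc1 was 14.7 to 42.9 CPM in EP LTi0, 0.2 to 31.3 in EP LTi4 and 0 to 6.31 in EP LTiP. It had no count in FL LTi0 and LTi4. C1qa was 7.72 to 47.4 CPM in EP LTi0 and 0.435 to 8.16 in FL LTi0. Adgre1 overlapped between these groups, at 15.3 to 67.2 and 17.8 to 53.7 CPM. The higher mean of 19 of the 19 measured list genes restates the list result. The sort excluded F4/80. Adgre1 reached 163 CPM in EP CLP, but edgeR did not call it between EP and FL CLP (adjusted p 0.217).

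Neutrophil granule genes were higher in the LTi0 and LTi4 libraries of FL, and RNA of the whole fetal liver was argued against, since 3 of the 6 FL libraries had Alb under 10 CPM and their lowest ratio of Mpo or Prtn3 to the highest EP library was 2.35 (136 against 27.5 CPM for Mpo, 30.1 against 12.8 for Prtn3), in a library with Afp at 6.37. Afp was 12.2 in another of the 3 and 34.0 in FL LTi0 replicate 2, against at most 16.98 in EP, so 2 libraries carry this argument. The 3 FL libraries standing apart were argued against as the cause (log2 fold change nearest to 0 without them -2.048). Granulocyte or monocyte precursors in these libraries cannot be told apart from untested transcription in FL LTi cells, since the higher mean of 15 and 17 of the 19 list genes in LTi0 and LTi4 restates the list result (estimated adjusted p 0.189 and 0.0189). The sort selected IL7Rα, α4β7 and RORγt and excluded Ly6G, and Ly6g had no count in FL LTi0 and LTi4. Mpo was 286 to 494 CPM in the FL CLP and LTiP libraries against 82.7 to 157 in FL LTi0 and LTi4. It was also 282 to 317 CPM in EP CLP and 143 to 188 in EP LTiP. Elane was uneven in FL LTi4, at 27.4, 0 and 0.815 CPM in replicates 1, 2 and 3.

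Several results differed between the tissues by the interaction test. For CLP to LTiP these were 4 genes, Lef1 (8.52), Hmgn3 (-1.85), Maf (-2.47) and Jaml (-1.77). For LTiP to LTi0 they were 21 genes, of which Ms4a6c (6.45), Hba-x (8.32), Cmah (6.38), Lef1 (-11.35), Itgam (-3.06), Ncf1 (-1.02), Tbc1d2 (-2.85) and Grifin (-2.84) are named. The values of Lef1 and Hba-x are model estimates that include a group without counts (FL LTiP and FL LTi0), not measured folds.

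In 14 of 178 tested groups of 4 libraries, 1 library stood far from the others by Dixon's test, where chance gives about 1 in 20. In EP LTi0 replicate 1, Itgb7 was 317.7 CPM (others 412.7 to 425.5), Cd8a 8.22 (others 0) and Ly6d 5.26 (0 to 0.175). In EP LTi0, Cavin2 was 6.14 in replicate 3 (others 0 to 0.808) and Lef1 59.7 in replicate 4 (34.9 to 38.9). In EP LTiP replicate 1, Cnn3 was 113 CPM (97.7 to 99.95), Rxrg 40.8 (53.4 to 55.8), Igll1 14.6 (3.77 to 4.68) and Stc1 39.5 (12.7 to 16.8). In EP LTiP replicate 2, Zcchc18 was 98.4 (61.5 to 63.6) and Agpat3 38.5 (53.7 to 54.97). In EP LTiP, Cd3g was 109 in replicate 3 (94.5 to 95.98) and Cmah 19.9 in replicate 4 (29.7 to 30.9). In EP LTi4 replicate 3, Themis2 was 101 CPM (78.7 to 81.8).

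Other splits of the same samples were counted for every comparison, the real split included. Between EP and FL, 1 of 35 splits called as many genes in CLP (next highest 17), LTiP (1), LTi0 (9) and LTi4 (5). For the EP steps 1 of 35 splits called as many, with the next highest at 1, 0 and 3. For the FL steps 1 of 10 splits called as many (next highest 9, 42 and 52), and 10 splits are too few to reach a share under 0.05. For the interactions 3 of 100, 1 of 100 and 100 of 100 splits called as many, while the highest of the other splits called 16, 4 and 26 against the real 4, 21 and 0. The split with 16 genes differed from the real one by the exchange of EP LTiP replicate 2 and FL LTiP replicate 3, which stood apart. The split with 26 set 7 EP libraries against all FL libraries and EP LTi0 replicate 4, nearly the tissues. Both point to a structure of the samples, which was not tested further.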

How the results depend on the processing

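The limma voom, 3-library and depth alternatives below were chosen only after the data were seen. No named gene reversed under the alternatives and leave-outs run, and no list under those run for lists (no run term, DESeq2 size factors, estimated correlation, fry). DESeq2 size factors kept every count within 1.5 times. The near-even balance of LTi0 against LTiP in EP, 51.4% higher, turned with DESeq2 size factors (49.1%) and without the filter (48.8%). It turned within the first run alone as well. The cause was not tested for any change below unless one is given.

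The DESeq2 Wald test called 509, 274, 255 and 339 genes between EP and FL in CLP, LTiP, LTi0 and LTi4, 452, 1761 and 181 in the EP steps, 409, 2381 and 451 in the FL steps, and 110, 235 and 121 in the interactions. It called 175 higher and 164 lower for LTi4 between tissues, against 7 and 16, and 848 and 913 for LTi0 against LTiP in EP, against 567 and 536. In simulated data DESeq2 called 64, 73 and 66 false genes where edgeR called 3, 2 and 1. Those counts were drawn with dispersions estimated by edgeR and without a run effect, so they cannot show which tool errs on the real data. Without the run term the counts were 66 for LTiP and 39 for LTi4 between tissues and 1 for the last interaction. Without the filter the FL step from LTi0 to LTi4 called 39.

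The first run alone, with fewer samples, called 2361 for LTiP between tissues, 480 and 38 for LTiP against CLP and LTi4 against LTi0 in EP, 1102 for LTiP against CLP in FL and 777 for its interaction. The balance turned in FL, with 187 higher and 915 lower against 136 and 21 over all libraries, and in its interaction, with 719 and 58 against 1 and 3. A lone FL library in these was assumed to vary as the other groups do. For LTiP it was replicate 3, which stood apart on the second principal component. The second run alone called 1 and 0 for LTi0 and LTi4 between tissues, 6 for LTi4 against LTi0 in EP, and 70, 351 and 1 for the FL steps.

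limma voom called 81 for LTi4 between tissues, 357 for LTiP against CLP in EP, 282 for LTi4 against LTi0 in FL, and 0, 32 and 2 in the interactions (745 unadjusted in the first). Its balance turned for LTi4 between tissues, with 52 higher and 29 lower against 7 and 16. It also turned for LTi4 against LTi0 in FL, with 91 and 191 against 41 and 18. For LTi0 against LTiP in EP, 49.9% of 1621 genes were higher, against 51.4% in the main fit. For LTiP against CLP in FL, 56.2% of 137 were higher, against 86.6%. limma voom shared 6 of the 21 genes called for LTiP between tissues. For CLP between tissues it called 143 and shared 87 of the 183. Leaving out the 3 FL libraries that stood apart gave 306 for CLP between tissues and 408, 1771 and 75 for the EP steps. It gave 244 and 20 for LTiP against CLP and LTi4 against LTi0 in FL, and 32 and 10 for the first 2 interactions. For LTiP, LTi0 and LTi4 between tissues the counts were 20, 27 and 24. Only 10 of 21, 15 of 24 and 12 of 23 genes were shared with the main fit there. With log2 depth as a covariate the counts were 56 for LTiP and 13 for LTi4 between tissues, and 15 and 34 for the first 2 interactions.

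Leaving out single libraries gave 95 to 227 (CLP), 6 to 67 (LTiP), 14 to 48 (LTi0) and 0 to 247 (LTi4) between tissues, 156 to 265, 663 to 1274 and 11 to 40 in the EP steps, 104 to 183, 968 to 1587 and 21 to 272 in the FL steps, and 2 to 9, 8 to 45 and 0 to 9 in the interactions. Of the 159 named entries 132 to 156 kept their call. limma voom kept 122, leaving out the 3 FL libraries 130, no filter 148, the depth covariate 151, no run term 153, and DESeq2 size factors and the DESeq2 Wald test 157 each. With fewer samples the first run kept 69 of 93 entries and the second 14 of 80. Of 150 list calls, 48 were kept with an estimated correlation; fry made 86 list calls, 82 of them shared.

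With a replicate block for sets of 4 consecutive library numbers, 1 library per population, the EP steps called 202, 863 and 12 genes, the FL steps 147, 1178 and 40, and the interactions 5, 15 and 0, all within 1.5 times. The genes shared with the main fit were 186 of 216, 784 of 1103 and 11 of 18 in the EP steps. In the FL steps they were 129 of 157, 1084 of 1367 and 32 of 59. In the first interaction 3 of the 4 genes were shared, and in the second 11 of 21. Lef1 lost its call in the first interaction, while its fitted log2 difference went from 8.52±1.27 to 8.34±1.38 (adjusted p 0.0128 and 0.0603 by edgeR). Of the 101 named entries of the steps and interactions the block kept 86. To compare the sets, deviations of log2 CPM from the group means were correlated between libraries of different populations within a tissue. Pairs of the same set had a mean correlation of 0.0301 and other pairs -0.0107, and the lowest same-set value was -0.0712. By this measure 21 of 28 libraries correlated best with a library of their own set. The share expected without sets was not computed, so this is a hint from the data and not the design. The 3 FL libraries that stood apart were of 1 set.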

Other observations

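All tests in this part were chosen only after the data were seen.

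For most genes of the LTiP to LTi0 step that were followed, the value in LTi4 differed from LTi0 toward LTiP. The genes were chosen for a difference between LTi0 and LTiP, which favours genes extreme in LTi0. On such genes another population would tend to lie back toward LTiP. The result therefore does not place LTi4 between LTiP and LTi0. Genes chosen by LTi4 against LTiP were not followed in LTi0. Genes were chosen in one tissue and followed in the other, so that the groups compared shared no library, although the run term and the spread came from 1 model of all samples. Of the 567 genes higher in LTi0 than LTiP in EP, 532 (93.8%) were lower in LTi4 than LTi0 in FL, where 50.9% of all genes were lower, with a mean log2 fold change of -0.82 (camera p 8.61e-34, 3.82e-06 with an estimated correlation). Of the 536 genes lower in EP, 446 (83.2%) were higher in LTi4 than LTi0 in FL, with a mean of 1.16 (8.73e-29, estimated 1.39e-06). Of the 510 genes lower in the FL step, 325 (63.7%, against 47.9% of all genes) were higher in EP LTi4, with a mean of 0.46 (1.81e-09, estimated 0.00290). Of the 857 genes higher in the FL step, 596 (69.5%) were lower in EP LTi4, with a mean of -0.14 (0.00153), which was not below 0.05 with an estimated correlation (p 0.174). Flt3 is an example, at 395 CPM in EP LTiP, 102 in LTi0 and 247 in LTi4. Compared directly, LTi4 and LTiP differed in 621 genes in EP (406 higher in LTi4 and 215 lower) and 393 in FL (301 and 92).

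Lef1 was 21 to 28.5 CPM in the EP CLP libraries, 3.37 to 49.8 in EP LTiP, 5.75 to 10.9 in FL CLP, 0 in all 3 FL LTiP libraries, 77.0 to 145 in FL LTi0 and 22.7 to 51.8 in FL LTi4. Transcripts of hepatocytes were uneven between FL libraries. Alb had no count in the EP libraries and reached 114 CPM in FL LTi0 replicate 1 and in FL LTi4 replicate 3, where Afp, the fetal serum protein, reached 169.8 and 186.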
